A study of Homo sapiens with 12 samples.

How the data were processed

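Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in human CD34+ haematopoietic stem and progenitor cells. Per the labels' protocols, the cells were transduced with lentivirus, the GFP-positive cells were sorted after 72 hours, nuclei were prepared before transposition, and libraries were made with a modified Nextera kit. The 12 libraries formed 6 groups of 2. RAD21 and SMC1A are subunits of cohesin, the ring complex that holds sister chromatids together and folds chromatin into loops. For each of these genes there were cells given an empty vector, the wild-type cDNA or a mutant cDNA, and the labels do not say which mutation was used. The titles tied the libraries into 4 sets of 3, 1 set per gene and replicate number, each set with 1 empty-vector, 1 wild-type and 1 mutant library. Empty-vector and wild-type libraries together are called controls.

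The deposited files were lists of accessible regions, 1 list per library, with 9 columns and no header. Reads were aligned to hg19, and the tools Bowtie and Picard were used, per the submitters' processing notes, which gave no versions. The peak caller, its settings, the handling of duplicates and any shift of reads for the transposase offset are not given in the sources used here. Each list was called by itself, as far as the separate lists show. The score that the authors deposited for each region, in column 7, is a whole number whose meaning the files do not name. It was used to describe, rank or filter regions within a list. It was also compared between lists, as the score of 300-bp regions, as a cutoff at the median of all lists and as means over libraries, although its scale may differ between lists. Columns 8 and 9 of the deposited lists hold values that behave as −log10 of a p-value, and the smallest value of column 8 lay just above 2 in all 12 lists, as an adjusted p of 0.01 would give. Region starts and widths moved in steps of a fixed size, and the narrowest regions spanned 300 bp. The lists gave no read numbers, so the depth of each library is unknown, and no counting interval or detection limit could be computed. A shorter list can come from fewer reads, from a lower share of reads in open chromatin or from fewer open regions, and the lists do not separate these.

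Regions were read as deposited, with chromosome Y left out throughout. Regions of all 12 lists that overlapped by at least 1 bp were merged, and a library was taken to call a merged region when 1 of its own regions overlapped it. Positions are given in hg19, counted from 1. No hg19 sequence or gene annotation was used here, so regions are named by position alone, and the planned comparisons of promoter share, transcription factor motifs, motif retention and gene lists were not run. The planned check for signal over the transduced cDNA needed annotated exons. It was replaced, after seeing the data, by a search for regions that all 4 libraries given the wild-type or mutant cDNA of RAD21 called and none of the other 8 did. The same search for the other gene and the position of 1 of the 8 crowded windows are not reported here.

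Numbers of regions were compared on the log2 scale with two-sided exact permutation tests over every split of the libraries into groups of the same sizes, with a threshold of 0.05. Retention was the percent of regions called in all 4 controls of a gene that both of its mutants also called, set against the same percent with every other pair of the 6 libraries in the mutants' place. Gains were regions called in both mutants and no control of a gene, or in all 4 mutants and none of the 8 controls. The regions to be named were fixed before the data were examined as up to 15 called in all 8 controls and no mutant, and up to 15 called in all 4 mutants and at most 2 controls, ranked by mean score. Retention by strength was computed over regions that all 4 replicate-1 controls called, split into 5 equal parts by the mean of their within-list score ranks, and was read in the 8 other libraries. A within-list index divided the median score of the regions called in all 12 libraries by the median score of the list's 300-bp regions, its weakest calls. Crowding was the percent of a list's regions in its 10 fullest windows of 1 Mb. These last 3 measures were chosen after seeing the data.

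Nothing in the labels says whether the 2 libraries of a group came from separate donors or cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels do not say what the shared title code of a set marks. Deviations from the mean of the 4 libraries of a kind (empty vector, wild type or mutant, both genes) were taken over regions in more than 1 and fewer than 12 libraries. They correlated at 0.15 to 0.55 between the empty-vector and wild-type libraries of a set, over 0.1 in 4 of 4 sets. The highest of these, 0.55, joined the 2 longest lists, with 41524 and 41516 regions. Between empty-vector and wild-type libraries of different sets the deviations correlated at −0.30 to 0.18. The code thus appears to pair the empty-vector and wild-type libraries of a set, by the data alone, although the ranges overlap. Between mutants and controls of a set, 1 of 4 correlations was over 0.1 with empty vector and 1 of 4 with wild type. Alternatives were a stricter score, covered bases in place of numbers, autosomes only, joining regions within 500 bp, exchange of labels within sets, each library left out in turn, an overlap of 50% of both regions, regions in at least 2 of the 4 controls and gains allowed in at most 1 control. A cutoff of 5 on column 8, removal of the crowded windows and removal of both SMC1A mutants were added after seeing the data.

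The code was tested on simulated data. All 200 regions set to be lost and all 200 set to be gained were found among 51785 simulated regions, with 464 regions called lost in total because others were absent from the simulated mutants by chance. With 4 libraries against 8 and a simulated SD of 0.7 on the log2 scale, 3.5% of 200 comparisons without a difference and 97.5% of those with a 4-fold difference gave a permutation p under 0.05. In the data, the log2 SD of the number of regions was 2.08 in the 4 mutants and 0.78 in the 8 controls. The simulation gave both groups the same SD, so its rates do not describe the comparison of mutants with controls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.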

Results

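ATAC-seq lists of accessible regions were compared in 12 libraries of human CD34+ haematopoietic stem and progenitor cells, to ask how chromatin accessibility differed between cells given a mutant cohesin subunit and cells given its wild-type form or an empty vector. For RAD21 and for SMC1A there were 2 empty-vector, 2 wild-type and 2 mutant libraries. The lists held between 719 and 41524 regions and covered between 0.542 and 31.0 Mb. Merging them gave 51785 regions, of which 14410 were called in a single library, 6521 in all 8 controls and 446 in all 12 libraries. The number of reads behind each list is unknown.

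RAD21, the gene transduced in 4 of the libraries, lies on chromosome 8. All 4 libraries given wild-type or mutant RAD21 called 8 regions that no other library called, and 7 of these lay on chromosome 8 between 117859501 and 117879225, with the other at chromosome X from 100056001 to 100058250. Within the stretch on chromosome 8, the libraries given RAD21 called 10, 7, 10 and 10 regions and the other 8 libraries called 0. The highest mean authors' score of these regions was 254 ± 180 (SD, n = 4), at 117866251 to 117866925. The next region at higher coordinates that all 8 controls called, from 117886201 to 117887550, was also called in both RAD21 mutants and in neither SMC1A mutant. Since the regions were chosen by which libraries called them, their presence does not check the labels. They were not compared with annotated exons here. The number of regions limited to these libraries was 18 without the RAD21 arm's empty vector replicate 1 and 13 without RAD21 wild type replicate 2.

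**Figure D1:**
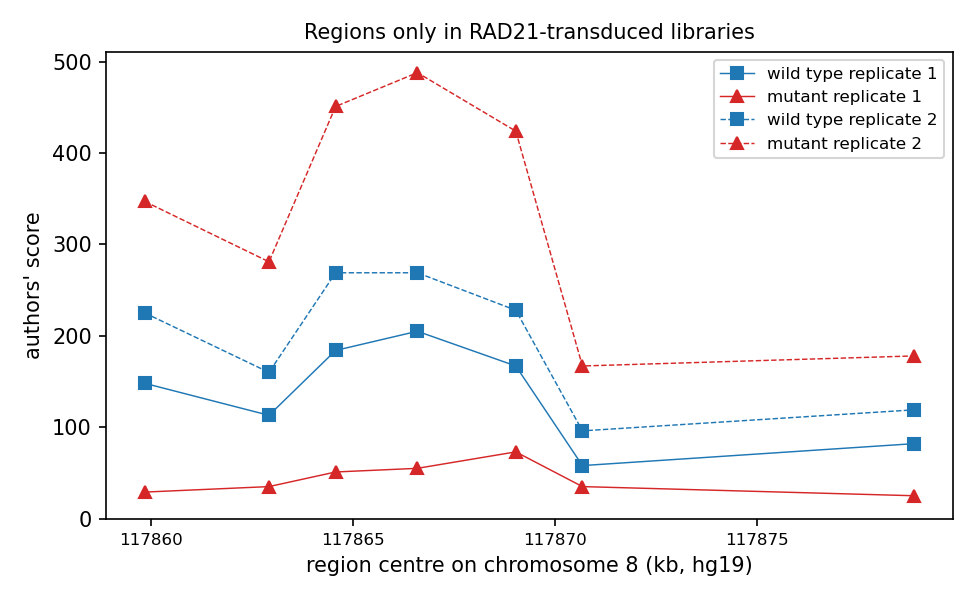
Authors' score (vertical axis, no unit given) of the 7 regions on chromosome 8 called in all 4 libraries given a RAD21 cDNA and in no other library, against the region centre in kb (hg19, horizontal axis). Each line is 1 library, blue squares for wild type and red triangles for mutant, solid for replicate 1 and dashed for replicate 2, and all 4 libraries have every region.

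Mutant libraries had fewer accessible regions than controls. The 4 mutants averaged 6815 ± 6741 regions (SD, n = 4) and the 8 controls 23943 ± 12384 regions (SD, n = 8). On the log2 scale the difference was −2.53, or 5.76-fold fewer regions, with an exact permutation p of 0.0141. The mutant had the shortest list in 4 of 4 sets. It held 35.3% and 60.03% of the geometric mean of its 2 controls in the RAD21 sets, and 6.77% and 6.33% in the SMC1A sets. Covered bases differed by −2.52 on the log2 scale, with an exact permutation p of 0.0141. The call rested on the SMC1A mutants, since without both of them the difference was −0.79 with an exact permutation p of 0.311. This set the 2 RAD21 mutants against all 8 controls, those of the SMC1A arm included. Against the 4 controls of their own sets the RAD21 mutants differed by −1.12, with an exact permutation p of 0.2. Among regions with a score above the median of all lists the difference between all 4 mutants and the 8 controls was −1.93, with an exact permutation p of 0.0667. The scale of the score may differ between lists. The median score of 300-bp regions was 13 to 34 in the controls and 31 and 41 in the SMC1A mutants. With a cutoff of 5 on column 8, added after seeing the data, the difference was −2.80, with an exact permutation p of 0.0141.

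**Figure D2:**
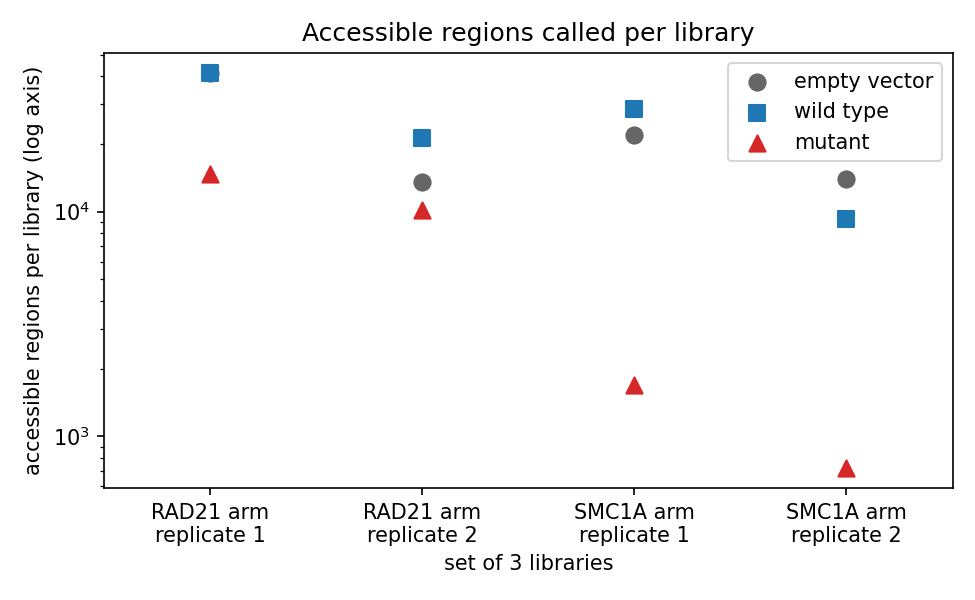
Number of accessible regions in each library (vertical log axis) by set of 3 libraries (horizontal axis), with grey circles for empty vector, blue squares for wild type and red triangles for mutant. The mutant is the lowest in all 4 sets, from 14669 regions in the RAD21 arm's replicate 1 to 719 in the SMC1A arm's replicate 2.

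Against each kind of control alone the difference was of similar size and did not pass the threshold. Mutants differed from wild type by −2.58 and from empty vector by −2.47 on the log2 scale, each with an exact permutation p of 0.0857, where the smallest possible was 0.0286. Without the RAD21 mutant replicate 1, the difference from empty vector was −3.14 with an exact permutation p of 0.0286. This was the only 1 of 8 such omissions to pass, and the others gave an exact permutation p of 0.0857 to 0.2. Against wild type none of 8 omissions passed, with an exact permutation p of 0.0571 to 0.171. Wild-type libraries averaged 25133 ± 13494 regions (SD, n = 4) and empty-vector libraries 22754 ± 13114 regions (SD, n = 4). Their log2 difference of 0.11 was smaller than the spread between libraries, with an exact permutation p of 0.886. Its direction changed to −0.20 without RAD21 wild type replicate 1, −0.02 without SMC1A wild type replicate 1, −0.09 without the RAD21 arm's empty vector replicate 2 and −0.07 without the SMC1A arm's empty vector replicate 2. No region was called in all 4 wild-type libraries and no empty-vector library. The reverse held for 2 regions, chosen after their values were seen, at chromosome 2 from 91799926 to 91800675 and chromosome 8 from 356626 to 357150, and 39 of the 70 splits of these 8 libraries gave as many.

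The shortest lists were those of the SMC1A mutants. The 2 SMC1A mutants had 1697 and 719 regions, a mean of 1208 ± 692 (SD, n = 2), against 18438 ± 8539 (SD, n = 4) in their controls. This was 15.3-fold fewer by the ratio of geometric means, with an exact permutation p of 0.0667, the smallest that 2 libraries against 4 can give. The 2 RAD21 mutants had 14669 and 10174 regions, a mean of 12422 ± 3178 (SD, n = 2), against 29449 ± 14286 (SD, n = 4) in their controls, or 2.17-fold fewer by the ratio of geometric means with an exact permutation p of 0.2. The effect of SMC1A minus that of RAD21 was −2.82 on the log2 scale. Exchange of the 4 sets between the genes gave an exact permutation p of 0.333, the smallest possible, so the difference between the genes could not be called.

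Regions shared by the controls were mostly retained in RAD21 mutants and mostly absent from SMC1A mutants. Of the 6521 regions in all 8 controls, the RAD21 mutants called 97.7% and 90.5%, and the SMC1A mutants called 21.6% and 7.48%. Within the RAD21 sets, 11977 regions were called in all 4 controls. Both mutants kept 67.5% of them, replicate 1 alone kept 85.7% and replicate 2 alone kept 69.98%, and 1420 were kept by neither. Of the 15 pairs of these 6 libraries, 2 gave a percent as low when set in the mutants' place, the mutants' own pair included. The other was empty vector replicate 2 with RAD21 mutant replicate 2, at 64.1%. In both genes, every pair but the mutants' own left at least 1 mutant among the 4 libraries that defined the regions. This favours a low rank for the mutants. The kept percent was 44.8% without the empty vector replicate 2, and 25.5% over regions of at least 2 of the 4 controls. Within the SMC1A sets, 7072 regions were called in all 4 controls, and both mutants kept 6.43%. Neither kept 5609 regions, or 79.3%. The mutants were the lowest of the 15 pairs, and the lowest other pair gave 30.8%. The list of SMC1A mutant replicate 2 could hold at most 10.2% of these regions whichever it called, so the low percent and its rank largely restate the length of that list. Without the SMC1A mutant replicate 2 the kept percent was 20.1%. It was 2.37% with an overlap of 50% of both regions and 2.65% over regions of at least 2 of the 4 controls.

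Retention rose with the strength of a region in the controls, over all 5 parts in the RAD21 mutants. In the SMC1A mutants it rose mainly in the strongest part. Of the 18345 regions that all 4 replicate-1 controls called, each of 5 equal parts by within-list score rank held 3669. The replicate-1 mutants shared their sets with these defining controls, and the replicate-2 libraries did not. Whether this raised the retention of the replicate-1 mutants was not tested. The RAD21 mutants called 100% and 99.5% of the strongest part, and the replicate-2 controls between 97.1% and 100%. The SMC1A mutants called 34.9% and 10.8% of it. In the weakest part the RAD21 mutants called 20.3% and 7.41%, against 15.8% and 51.0% in the replicate-2 controls of their own arm and 19.98% and 7.36% in those of the other. RAD21 mutant replicate 2 was lower than both controls of its set in all 5 parts. In the part next to the weakest it called 17.5%, against 17.9% to 83.7% in the replicate-2 controls. In every other part SMC1A wild type replicate 2, with 9288 regions against 10174, called fewer, as in the middle part with 32.8% against 41.8%. RAD21 mutant replicate 1, with 14669 regions, called more than its arm's empty vector replicate 2, with 13542, in all 5 parts. Retention was not adjusted for the length of the lists. The SMC1A mutants each called 35 regions, or 0.954%, of the weakest part. In the part next to the strongest the SMC1A mutants called 2.43% and 0.927%, against 67.5% to 99.9% in the replicate-2 controls.

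**Figure D3:**
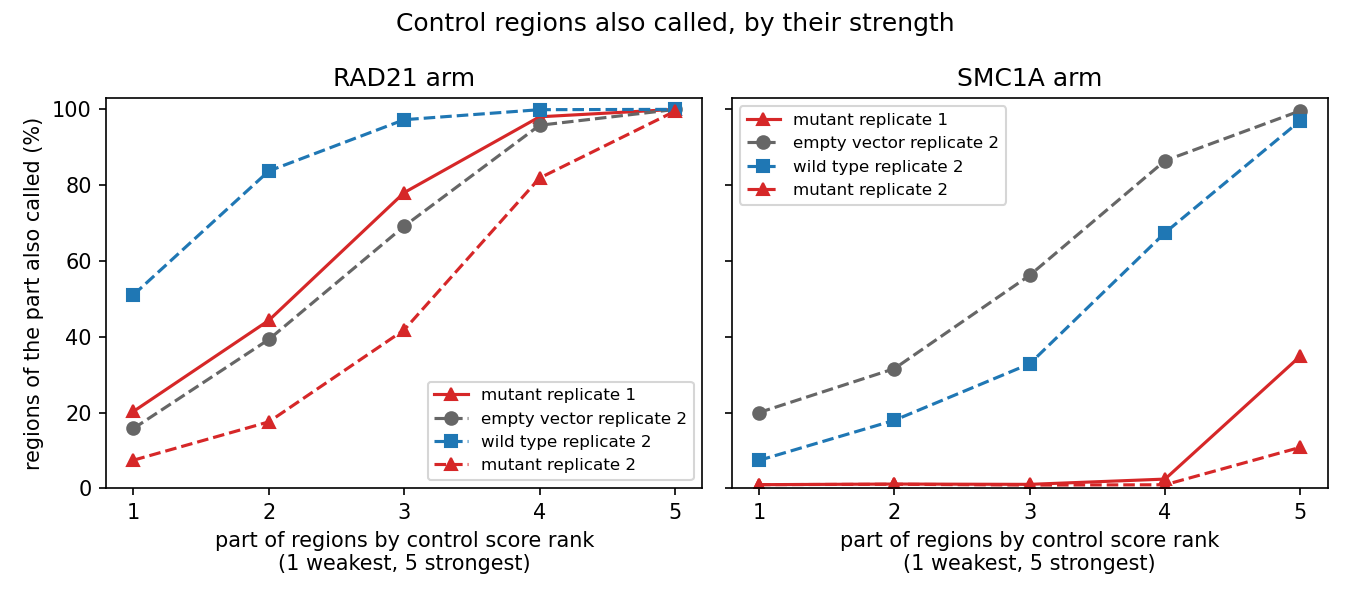
Percent of regions also called (vertical axis) in each of 5 equal parts of the 18345 regions of the 4 replicate-1 controls, from weakest (1) to strongest (5) by mean within-list score rank, in the RAD21 arm (left) and the SMC1A arm (right). Red triangles are mutants, blue squares wild type and grey circles empty vector, solid for replicate 1 and dashed for replicate 2, and the SMC1A mutants stay at or under 2.43% in parts 1 to 4 and reach 34.9% and 10.8% in part 5.

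Regions called in all 8 controls and in no mutant numbered 102, or 1.56% of the regions of all 8 controls. Redrawing every list at its own length, from how often each region was called, gave between 226 and 300 such regions in 100 redraws, all more than the 102 observed. Without both SMC1A mutants the number was also 102, so none of the 8-control regions absent from both RAD21 mutants was called in an SMC1A mutant. The highest mean scores among them were those of chromosome 17 from 62403601 to 62404575, with a score of 72.1 ± 51.9 (SD, n = 8), chromosome 14 from 102197326 to 102198150, with 68.8 ± 52.1 (SD, n = 8), and chromosome 17 from 76194751 to 76195725, with 67.5 ± 43.1 (SD, n = 8). Next came chromosome 12 from 132303451 to 132304350, chromosome 2 from 25538776 to 25539600, chromosome 11 from 66360001 to 66360975, chromosome 2 from 2060701 to 2061600, and chromosome 13 from 99964501 to 99965325. They were followed by chromosome 1 from 35384551 to 35385300, chromosome 2 from 99365251 to 99366150, chromosome 4 from 14878726 to 14879550 and chromosome 2 from 129076126 to 129077025. The last of the 15 named were chromosome 10 from 33950476 to 33951600, chromosome 3 from 40341076 to 40341900 and chromosome 8 from 139203976 to 139204875. These regions were of middling strength, with a median score percentile of 52.8 within the control lists, against 80.3 for all regions of the 8 controls. The number was 622 without the RAD21 mutant replicate 1, 330 without SMC1A wild type replicate 2, 218 without the SMC1A arm's empty vector replicate 2 and 216 without the RAD21 arm's empty vector replicate 2.

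Few regions appeared only in mutants. Of the 506 regions in all 4 mutants, 446, or 88.1%, were also in all 8 controls. A single region, at chromosome 21 from 10838926 to 10839450 with a score of 37.0 ± 7.75 (SD, n = 4), was called in all 4 mutants and no control. A region at chromosome 14 from 19001176 to 19001775, with a score of 41.5 ± 17.3 (SD, n = 4), was called in all 4 mutants and 2 controls. Both RAD21 mutants and none of their 4 controls called 14 regions, and 10 of the 15 pairs of these libraries, the mutants' own included, gave as many. Both SMC1A mutants and none of their controls called 5 regions, and 9 of the 15 pairs, the mutants' own included, gave as many. Chosen after their values were seen, these 5 were the region on chromosome 21, chromosome 9 from 68419201 to 68419875, chromosome 10 from 39149101 to 39149400, chromosome 4 from 49289176 to 49289700 and chromosome 2 from 91810951 to 91811475. The region on chromosome 4 lies in the window from 49000001 to 50000000, the fullest of both SMC1A mutants. That on chromosome 14 lies in 1 of the 10 fullest windows of SMC1A mutant replicate 2. Whether any of these regions is sequence present in many copies was not analysed. The counts of gained regions rested on single libraries. The RAD21 count was 237 without mutant replicate 2, 90 without mutant replicate 1, 27 without wild type replicate 1 and 26 without empty vector replicate 1. The SMC1A count was 33 without mutant replicate 2, 32 without mutant replicate 1, 23 without empty vector replicate 1 and 8 without empty vector replicate 2.

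The regions of the SMC1A mutants lay crowded in few places. The 10 fullest windows of 1 Mb held 10.3% and 22.7% of their regions, 2.86% and 3.02% of those of the RAD21 mutants, and between 1.80% and 4.18% of those of the controls. Mutants and controls differed by 7.05 percentage points, with an exact permutation p of 0.0323. Without SMC1A mutant replicate 1 the exact permutation p was 0.0970, and without SMC1A mutant replicate 2 the difference was 2.73 percentage points with an exact permutation p of 0.0970. Autosomal windows among the 10 fullest of both SMC1A mutants numbered 7. They were at chromosome 4 from 49000001 to 50000000, chromosome 10 from 42000001 to 43000000, chromosome 16 from 46000001 to 47000000 and from 33000001 to 34000000, chromosome 2 from 92000001 to 93000000 and from 133000001 to 134000000, and chromosome 11 from 51000001 to 52000000. The SMC1A mutants called 141 and 137 regions in these 7 windows. The controls called between 116 and 172 there and the RAD21 mutants 153 and 140, although the whole lists ranged from 719 to 41524 regions.

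**Figure D4:**
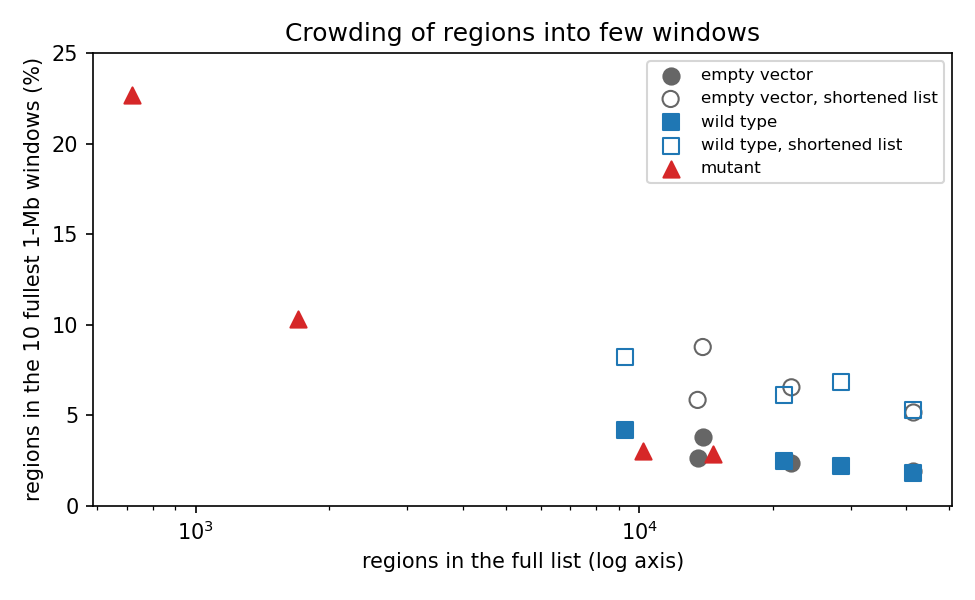
Percent of a library's regions in its 10 fullest windows of 1 Mb (vertical axis) against the number of regions in its list (horizontal log axis). Filled grey circles are empty vector, filled blue squares wild type and red triangles mutant, open symbols are the control lists shortened to the 719 regions of highest score, and the SMC1A mutants reach 10.3% and 22.7% while the shortened control lists stay at or under 8.76%.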

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

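The median region width was 525 bp in the SMC1A arm's empty vector replicate 2 and 600 bp in the other 3 empty-vector libraries. It stood out because the other 3 values were equal, and widths move in steps of a fixed size, so a single step sets the gap. For values without ties, chance would mark about 1 group in 20, and that rate was not measured for values that move in steps. Over all measures 30 groups were tested, and this was the 1 library marked.

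All tests of the shorter mutant lists below were chosen after the result was seen. The mutant had the shortest list in 4 of 4 sets, which argues only against differences that all 3 libraries of a set share. Handling of the mutants apart from the controls of their sets was not tested and stays open. If the score counted reads, fewer reads alone would be expected to give the weakest calls a lower score in mutants. The files do not name what the score is, and on another scale the direction could differ. The log2 score of 300-bp regions was higher by 0.59 over all mutants, with an exact permutation p of 0.0444 over all splits and 0.0988 within sets. By gene it was higher by 0.21 ± 0.25 (SD over 2 sets) for RAD21 and 0.98 ± 0.74 (SD over 2 sets) for SMC1A. These 3 forms of the comparison were looked at, with decision rules that were revised after the values were known, and they give no firm answer, so fewer reads stay open. Weaker signal over background cannot be told apart either. The within-list index was lowest in the mutant of every set, with an exact permutation p of 0.0123 within sets, the smallest possible, but in 26 of the 28 pairs of controls the longer list also had the higher index, so the index largely restates the length of the list. Loss of accessibility in cells with mutant cohesin, whose measured counterpart is the difference of −2.53, cannot be told apart from poor transposition or dying cells, because the lists hold no measure of library quality apart from the regions.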

How the results depend on the processing

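Of 66 alternatives other than leaving out a library, 56 kept the direction and the side of the threshold, or the size where there was no test. Part of this was fixed in advance. The smallest possible exact permutation p was 0.0667 within 1 gene and 0.333 between the genes, so only the direction could change there. Exchange of labels within sets leaves kept and gained regions as they are, and it was counted among those that kept the size. Planned promoter, motif and gene list comparisons, and the exon form of the cDNA check, were not run. The cause of each change below was not tested. With a score above the median of all lists, mutants minus controls was −1.93 (exact p 0.0667) and wild type minus empty vector −0.29. Without both SMC1A mutants, chosen after seeing the data, it was −0.79. With an overlap of 50% of both regions, RAD21 mutants kept 53.8% and SMC1A mutants 2.37%, and gains numbered 107 for RAD21 and 53 for SMC1A. Over regions of at least 2 controls these were 25.5% and 2.65%. Both SMC1A values are counted among the 56, since they moved by less than the SD between the mutants, although by over 1.5 times. Allowing 1 control, gains numbered 42 and 27. Allowing 1 other library, 18 regions were limited to libraries given RAD21.

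Leaving out each library in turn gave −3.19 to −1.74 for mutants minus controls (exact p 0.00909 to 0.0424), −3.14 to −1.69 against empty vector, −3.25 to −1.80 against wild type and −0.20 to 0.52 for wild type minus empty vector. Kept percents ranged from 44.8 to 85.7 for RAD21 and 4.49 to 20.1 for SMC1A. Gains ranged from 15 to 237 for RAD21, 5 to 33 for SMC1A and 1 to 2 for both genes, lost regions from 102 to 622, and RAD21-limited regions from 8 to 18. The within-list index ranged from −2.24 to −1.35 (exact p 0.0545 without SMC1A mutant replicate 1 and 0.0606 without replicate 2) and the crowding difference from 2.73 to 9.33 percentage points.

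Deviations of libraries of a set correlated at −0.51 to 0.55 with a median of 0.07, over 0.1 in 6 of 12 pairs, of which 4 were wild type with empty vector. Of pairs across the 2 genes, 9 of 24 were over 0.1, up to 0.64, and of pairs across the sets of 1 gene 2 of 12 were. The title code appears to pair wild type with empty vector and does not clearly pair mutants with controls. With this replicate block, wild type minus empty vector stayed at 0.11 (exact p 0.75), mutants minus controls stayed at −2.53 (exact p 0.0123), mutants minus wild type at −2.58 (exact p 0.125), mutants minus empty vector at −2.47 (exact p 0.125), and no call on the number of regions changed. Against 1 kind of control, the 16 exchanges within sets can give no exact p under 0.125, and within 1 gene the 9 exchanges none under 0.111. No call could therefore appear in those comparisons. The score of 300-bp regions lost its call (exact p 0.0444 and, within sets, 0.0988). In mutants minus controls the median width, −65.6 bp, and the percent of regions at the ceiling of column 8, −7.62 percentage points, gained one (exact p 0.107 and 0.0848 and, within sets, 0.0370 and 0.0123). Read depth is unknown, so what it limits could not be computed.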

Other observations

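Of the tests in this part, those of the transduced regions, of crowding, of retention by chromosome, of list lengths and of shared retention were chosen after the result was seen. Retention by chromosome was also read. The SMC1A mutants kept 37.1% and 17.6% of the 8-control regions of chromosome 4 and 9.40% and 2.01% of those of chromosome 20, while the RAD21 mutants kept 98.2% and 93.2% on chromosome 4 and 98.0% and 86.6% on chromosome 20. Without the crowded windows the SMC1A mutants kept 34.7% and 14.6% on chromosome 4. Over the 22 autosomes, which are not independent replicates, the kept percents of the 2 SMC1A mutants went together (Spearman's rho 0.61, permutation p 0.00332, adjusted 0.0199 over 12 correlations; Pearson's r 0.79, permutation p 1e-05, the smallest possible, adjusted 0.00012), and r was 0.63 without the 2 chromosomes farthest from the median. Those of the 2 RAD21 mutants also did so (rho 0.52, permutation p 0.0146, adjusted 0.0439; r 0.59, permutation p 0.00389, adjusted 0.0118), with r 0.35 without the 2 farthest chromosomes. Of the 4 pairs of a RAD21 with an SMC1A mutant none passed, with a lowest adjusted permutation p of 0.0762 for rho and 0.142 for r. Control strength was not matched between chromosomes.

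The regions limited to libraries given a RAD21 cDNA may be DNA of the transduced cDNA itself, aligned to the exons of the gene. Of these regions, 7 lay within a stretch of 50 kb. The most for any other 4 libraries was 4, leaving out the 4 given a cDNA of the other gene. As for their number alone, 25, or 5.05%, of the possible choices of 4 libraries gave as many, with a median of 0. Overlap with exons was not analysed here, and a change at the gene itself stays open. Within its own list, the median score of these regions was 1.25 and 14.1 times that of the weakest calls in the RAD21 mutants, and 5.78 and 8.02 times in the RAD21 wild-type libraries.

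The SMC1A mutants' crowding was not reached by short lists of strong regions, since control lists shortened to 719 regions of highest score had at most 8.76% in their 10 fullest windows, against 22.7% in SMC1A mutant replicate 2. Sequence present in many copies could give calls without accessibility, and the number of regions in the autosomal crowded windows, 116 to 172 over the 12 libraries, moved far less than the length of the list. However, only 55.4% of the 130 merged regions that either SMC1A mutant called in all 8 crowded windows, and 59.2% of the 120 in the autosomal ones, were called in at least 6 of 8 controls, and copy number was not analysed here, so this cannot be told apart from a change in the cells. No biological explanation was tested.

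Of 100 drawn splits of the 12 libraries, only the real one, 1 split, gave as many as 102 regions in 8 libraries and not in the other 4, and the highest other gave 14. This does not exclude chance, because a split that puts a very short list among the 8 can hold almost no such region, and the splits ignored the sets. The lengths of the lists alone stay open too: 100 of 100 redraws of the lists at their own lengths gave as many, between 226 and 300. All gave more than the lists did, so the redraws describe the lists only roughly and decide nothing. For regions of all 4 mutants and no control, 20 of 100 splits gave at least the 1 observed, and the highest other gave 141, so a chance split could not be excluded. The redraws gave 0 such regions in all 100, which excludes nothing for the same reason.

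A hypothesis was that the same regions are kept in RAD21 and SMC1A mutants beyond what control strength gives. Within strata of control strength, and without the crowded windows, the mean log2 odds ratio of the 4 pairs of a RAD21 with an SMC1A mutant was 5.89, the highest 1 of 36 arrangements of the libraries, against 4.98 for the highest other. Whichever the RAD21-arm library, pairs with an SMC1A mutant gave 1.65 to 7.51 and pairs with an SMC1A-arm control 0.06 to 1.38. The rank among the 36 therefore overstates the evidence, since only the choice of RAD21-arm libraries bears on the hypothesis. The RAD21 arm's empty vector replicate 2 gave 2.92 with SMC1A mutant replicate 1, where the RAD21 mutants gave 6.16 and 4.71, and 4.78 with SMC1A mutant replicate 2, where they gave 5.19 and 7.51. A difference in library quality that the mutants share was not tested and stays open.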
